A study of Mus musculus with 2 samples.

How the data were processed

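RNA from 2 sorted fractions of the mouse line 4T1 (SP and non-SP, 1 sample each) was hybridized to an Agilent one-colour mouse expression array, design 028005, with Cy3-labelled cRNA made with a low-input amplification kit, per the labels' protocols. The labels' extraction protocol speaks of tissue as the source of RNA while the other labels name a cell line, and whether the cells came from culture or from tumours is not given in the sources used here. The scanner files hold linear intensities made by the authors with Agilent Feature Extraction. The version is 10.7.1.1, protocol GE1_107_Sep09, per the file headers, and 9.5.1.1 per the submitters' processing notes; the cause of this mismatch is unknown. Per the file headers, the processed intensity is background-subtracted with spatial and multiplicative detrending, and dim spots carry surrogate values. It is not normalized between arrays. The deposited flags mark spots well above background, saturated or outlying. A deposited table of the whole series holds 1 intensity per probe and array on a linear scale. Its 2 columns have the same median (20.1) and, once sorted, differ by at most 0.022%, which is what quantile normalization gives, although its method is not stated. Each column correlated with the log2 processed signals of its own array at 0.9999 across probes, so scale and direction are known.

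The main values were log2 processed signals minus the 75th percentile of each array over the 59305 non-control spots. The 75th percentile was 320 intensity units in SP and 222 in non-SP, and the median local background was 66 and 67 units. Population outlier spots (128 in SP, 176 in non-SP) were left out on both arrays, no spot was flagged as non-uniform, and spots of a probe were averaged. Of 55681 distinct probes, 27235 took a current gene symbol through their accession, 3581 through their name and 565 through a unique synonym, using RefSeq's gene table for GRCm38.p6 for names only. The other 24300 kept the name in the file. The value of a gene is the mean over its probes that are well above background on both arrays (19173 genes). Of 5198 genes with more than 1 such probe, 1923 had probes of opposite sign, and among 183 such genes with a 2-fold difference 14 did. Genes detected on 1 array only were given a bound, and 43 genes whose probes were detected on opposite arrays were left out.

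With 1 array per group no test across samples was possible, and the number of arrays limits the precision. The spot SD came from 239 of the 399 non-control probes spotted 10 times, namely those well above background on both arrays. It was interpolated on signal, held constant below the dimmest sixth, and divided by the square root of the number of probes. For 33 gene lists fixed before the data were examined, the median difference of the measured members was placed among 10000 random lists of the same size, drawn from 40 classes of mean signal. Lists outside percentiles 2.5 to 97.5 are described as departing from random lists, as a description of these 2 arrays. The rule for named genes was also fixed beforehand. It took the 15 largest differences in each direction among genes with symbols other than clone, predicted or accession names whose measured probes agreed in sign, the 5 largest bounds in each direction, up to 4 members of each list with the largest differences, and Abcg2, Abcb1a, Abcb1b, Cd44, Cd24a, Aldh1a1, Ly6a, Itga6 and Prom1. Genes with a bound that are list members are named in addition.

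The gene caller and list percentiles were tested on simulated data with 20502 genes, of which 200 had a set change. Both simulated arrays were built from the SP array, with its detection flags and with noise from an assumed formula. The changed genes were drawn from the brighter genes only, so recovery of changes in dim genes was not tested. All genes changed by 1.5 or 2.5 log2 units passed the 2-fold limit (100%), 26 unchanged genes passed it, and 5.5% of random lists lay outside the limits.

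Alternatives chosen before the data were examined were normexp background correction (limma 3.58.1, offset 50), no background correction, scaling to the median, quantile normalization, a loess fit of the difference on intensity (span 0.3), no filter and a stricter filter on dim probes, outlier spots kept, the brightest probe per gene, and the authors' processed intensities. Removal of a probe GC trend and scaling to the E1A spike-in probes were added after seeing the data. The latter subtracted from each array the median log2 signal over all spots of the E1A probes that were well above background on both arrays. Like scaling to the median, it adds a constant to all differences and so cannot change the percentile of a list. Other analysis used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and statsmodels 0.14.6, with R 4.3.3 for limma. Coordinates are those of the scanner files (mm9) and were not converted.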

Results

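Gene expression was measured in 2 sorted fractions of 4T1, a mouse mammary carcinoma cell line, named SP and non-SP. SP is the usual abbreviation for a side population, cells that keep out a DNA-binding dye and are gated on that property, although the sample labels do not spell the term out. The stated purpose was to set the expression profile of the SP fraction against that of the non-SP fraction. Each fraction was represented by 1 one-colour Agilent array, so every difference below is a comparison of 2 arrays, with no replicate error and no p-value. Each array carried 59305 non-control spots, of which 52.6% in SP and 50.9% in non-SP were well above background. No spot was saturated. The error given is the spread between repeated spots of a probe, as the spot SD of the log2 difference. It was 0.32 in the dimmest sixth of the repeated probes and 0.06 in the brightest sixth. The spot SD leaves out variation in culture, sorting, RNA preparation, labelling and hybridization. It also leaves out disagreement between different probes of a gene, which can be larger. For example, the 2 Atf4 probes had 0.44 and 1.52, with a spot SD of 0.04. Signals are log2 values relative to the 75th percentile of each array, and differences are SP minus non-SP.

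The 2 fractions had similar profiles, with a correlation of 0.984 across the 19173 genes measured on both arrays (genes are not independent replicates). Genes of cell division, replication-dependent histones and the drug transporter Abcg2 were higher in SP. Genes of the hypoxia and interferon responses lay mostly lower in SP relative to other genes of like signal. At least a 2-fold difference was seen for 421 genes higher in SP and 597 genes lower in SP, and at least a 4-fold difference for 35 and 47 genes. The counts of 2-fold genes depended on the treatment of dim signals: they were 196 and 145 with normexp, 194 and 129 without background correction, and 1243 and 2433 with no filter on dim probes. Spot-to-spot noise alone, drawn around no difference, gave on average 2.27 higher and 2.30 lower genes at the 2-fold limit. The drawn noise may be too small for dim genes. It was taken at a gene's mean signal over both arrays and held constant below the dimmest sixth. The balance of directions depended on the scaling: genes higher in SP made up 41.4% of the 2-fold genes here, 55.5% after quantile normalization, 60.3% after a loess fit on intensity, 78.5% after scaling to the median, and 92.4% after scaling to the spiked-in control RNAs. Scaling to the median moved all differences up by 0.23 and scaling to the spike-ins by 0.43, so direction is stated relative to the other genes of the arrays. The 0.43 is the difference between the medians of all spike-in spots, whereas the median difference of the 8 spike-in probes was -0.38, with single probes between -0.72 and -0.30. List medians within that range have no settled sign relative to the spike-ins.

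**Figure D1:**
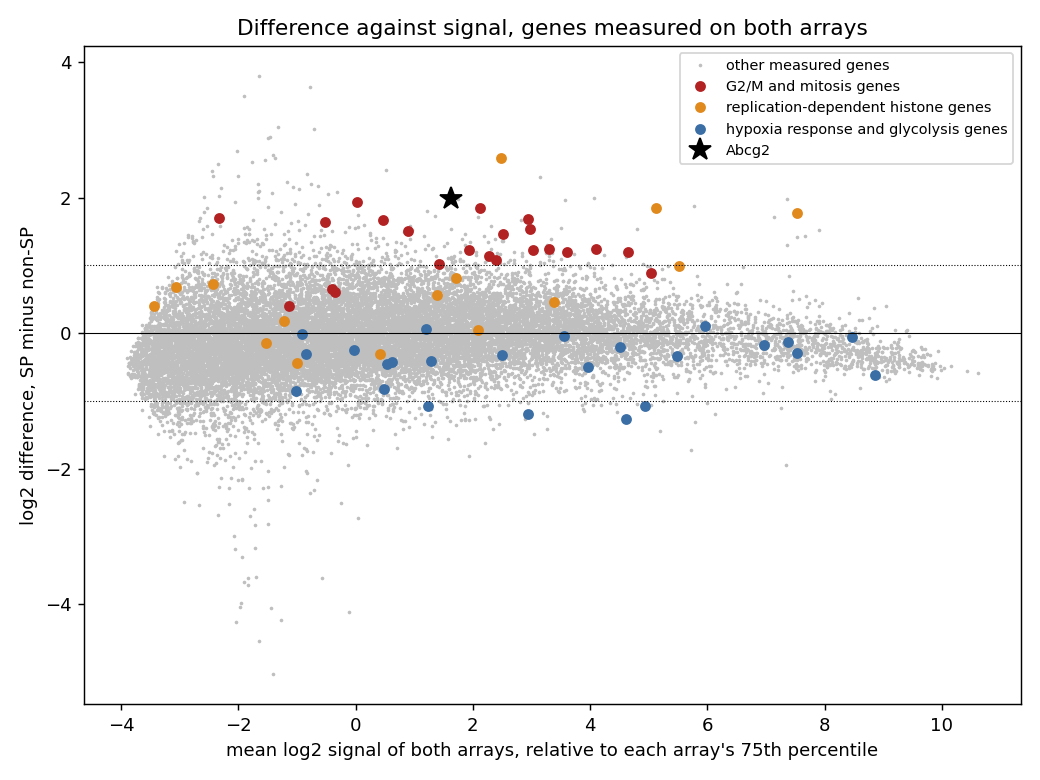
Difference between SP and non-SP (vertical axis, log2) against the mean signal of both arrays (horizontal axis, log2 relative to the 75th percentile of each array) for the 19173 genes measured on both arrays. Each point is a gene, dotted lines mark a 2-fold difference, and all 22 measured G2/M and mitosis genes lie above 0, while 22 of the 24 hypoxia and glycolysis genes lie below 0 with this scaling (their median is 0.10 with spike-in scaling).

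Abcg2, the efflux pump whose activity is the classical basis of dye exclusion by side population cells, was higher in SP by 1.98 on the log2 scale (3.94-fold, spot SD 0.08, 1 probe). Its normalized signal was 2.61 in SP and 0.64 in non-SP. The Abcg2 probe targets an mRNA and maps to chromosome 6, positions 58642312 to 58642371, in the mm9 build named in the file headers. No other measured member of the list of efflux transporters was at least 2-fold higher. Abcc3, a transporter of conjugated anions, had a difference of -1.48 (2.79-fold lower in SP). Abcg1, a sterol transporter, had a difference of -1.096 close to background, which was under 2-fold with 7 of its 11 alternative settings. The P-glycoprotein gene Abcb1a was dim with a difference of -0.56 (spot SD 0.31), and its paralog Abcb1b differed by 0.13 (spot SD 0.08). Abcc10 had a value of -0.73. Of the 12 measured members of the ABC transporter list, 1 was at least 2-fold higher, 2 were at least 2-fold lower and 9 differed by less. The median of the list was -0.12, at percentile 31.1 of 10000 random gene lists of the same size and like signal. Of the members not measured on both arrays, Abcb5 was well above background in non-SP only, with a bound of 3.40, Abca1 in SP only, with a bound of 0.38, and 4 on neither array.

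Genes of mitosis were higher in SP. All 22 measured members of the G2/M and mitosis list had higher values in SP, 18 of them by at least 2-fold, and the median difference was 1.24 (quartiles 1.101 and 1.617, 2.36-fold at the median). This median lay above all 10000 random lists, whose central 95% ran from -0.20 to 0.23. Cyclin B1 (Ccnb1), the activating partner of the mitotic kinase, was higher by 1.94, with its 3 probes between 1.83 and 2.08. Topoisomerase II alpha (Top2a) was higher by 1.85, the spindle checkpoint kinase gene Ttk by 1.69 and the centromeric histone gene Cenpa by 1.68. Ttk was dim, and its difference was 0.52 without background correction. Aurkb and Cenpf, also on the list, were well above background in SP only.

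Genes of DNA replication were higher by a smaller amount. The G1/S and DNA replication list had a median of 0.47 over 23 measured genes, 20 of them above 0, and this also exceeded all 10000 random lists. Only Chaf1a, a chromatin assembly factor gene, reached a 2-fold difference (1.04). Rrm1, a ribonucleotide reductase subunit gene, had 0.99, Gins2 had 0.97 and the helicase subunit gene Mcm5 had 0.87. Replication-dependent histones had a median of 0.57 over 15 measured genes, at percentile 100, with 3 genes at least 2-fold higher and 12 under 2-fold. Linker histone H1f5 (Hist1h1b on the array) was higher by 2.59, H2ac4 (Hist1h2ab) by 1.84 and H2ac11 (Hist1h2ag) by 1.78, while H4c4 (Hist1h4d) had 0.9962, just under the limit. Histone genes are near-identical copies, so their probes may not tell them apart. The histone median was 0.15 with normexp background correction and 0.16 without background correction.

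Genes of the hypoxia response and glycolysis lay lower in SP with this scaling. Their median was -0.33 over 24 measured genes (quartiles -0.67 and -0.16), at percentile 0.18 of the random lists, and 22 of the 24 were below 0. The 4 that were at least 2-fold lower were the pH regulator Car9 (-1.27), the mitophagy receptor gene Bnip3 (-1.19), the aldolase gene Aldoc (-1.08) and the angiogenic factor gene Vegfa (-1.07). With spike-in scaling the median of the list became 0.10 and none of these 4 reached 2-fold. Bnip3, Aldoc and Vegfa were under 2-fold with 4, 4 and 5 of the 12 alternatives, among them normexp, no background correction and scaling to the median. The fibroblast marker list, included as a check for another cell type, had a median of -0.47 over 9 measured genes. It lay at percentile 2.66, inside the central 95% of random lists, and outside it with 5 of the 12 alternatives. Its 2-fold members were the collagen VI chain genes Col6a1 (-1.41) and Col6a2 (-1.01). Col6a2, with 1 of its 2 probes measured, was under 2-fold with 8 of the 12 alternatives, and Col6a1 with spike-in scaling.

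The interferon response list had a median of -0.37 over 22 measured genes, at percentile 0.20, with 16 genes below 0 and none at a 2-fold difference. The largest values were those of Bst2, which tethers budding virus (-0.89), Ifi44 (-0.88), the oligoadenylate synthetase gene Oas2 (-0.69) and Ifit3 (-0.63). With spike-in scaling this median became 0.06, a sign that the spread of the spike-in probes does not settle. Ifi209 (Pyhin1 on the array), which is not on the list, had a difference of -3.62 (1 of its 3 probes measured on both arrays). Its difference was -1.24 when all probes entered regardless of background.

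The measured markers of mammary and breast cancer stem cells did not depart, as a group, from random lists. Of the 22 genes listed, 13 were measured on both arrays. Of the others, 1 was well above background in SP only, 1 (Cxcr4) in non-SP only and 7 on neither array. The measured genes had a median of -0.08, at percentile 27.4. Of these 13, 1 was at least 2-fold lower, 0 at least 2-fold higher and 12 under 2-fold. The adhesion receptor Cd44 differed by 0.09 (4 probes between -0.15 and 0.27, spot SD 0.04). Cd24a differed by -0.20 (spot SD 0.06), which was 0.23 with spike-in scaling. Ly6a, which encodes Sca-1, had 0.76 and the integrin gene Itga6 had -0.44. Aldh1a1 was near background on both arrays with 0.01 (spot SD 0.32), and neither of the 2 Prom1 probes was well above background on either array. The 2-fold lower member was the aldehyde dehydrogenase gene Aldh3a1 (-1.08), which was under 2-fold with 5 of the 12 alternatives and had -0.59 on its brighter probe. Itgb3, with 1 of its 2 probes measured, had -0.99, and -1.70 with no filter on dim probes. Pluripotency factors had a median of -0.37 over 9 genes, at percentile 1.78, and 7 of the 9 were below 0. Nanog had -1.49 and Klf2 had -0.87, whereas Klf5 had 1.13 and Myc 0.77. This list lay inside the central 95% of random lists with 4 of the 12 alternatives, and its median was 0.06 with spike-in scaling. Mouse Nanog has many pseudogenes, and its single probe may not separate their transcripts.

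Epithelial junction and identity genes had a median of 0.20 over 20 measured genes, at percentile 98.2, with 15 above 0 and none at 2-fold. Their largest values were those of the tricellular junction gene Marveld2 (0.91), Ovol1 (0.86), the claudin gene Cldn4 (0.70) and occludin (Ocln, 0.63). Ovol1 was dim and had 0.17 without background correction. Percentile 98.2 became 96.3 at the lowest, with the filter on dim probes changed. Mesenchymal transition genes had a median of -0.17 over 16 genes (percentile 25.2), with fibronectin (Fn1) at -0.97, Snai1 at -0.82, S100a4 at -0.80 and Mmp9 at 0.71. Luminal mammary genes had a median of 0.12 (percentile 94.3, Gata3 0.64, Prlr -0.63) and basal genes one of -0.32 (percentile 5.29, Itgb4 -0.85, Krt14 0.66). The dim gene Cnn1 (-1.07) was the only basal member at least 2-fold lower, and was under 2-fold with 7 of its 11 alternatives. Neither lineage list lay outside the central 95% of random lists, although the basal list was at percentile 2.20 and the mesenchymal list at 2.19 with the stricter filter and with no filter on dim probes, respectively.

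The unfolded protein response list had a median of 0.21 over 20 genes, at percentile 97.9, with the glutathione-degrading enzyme gene Chac1 at 1.36, the transcription factor gene Atf4 at 0.98, Herpud1 at 0.94 and the chaperone gene Dnajb9 at -1.12. Dnajb9 was under 2-fold with 5 of the 12 alternatives, and Atf4 had 0.44 on its brightest probe. The immediate early and heat shock list had a median of 0.20 over 19 genes, at percentile 97.7. Its members Junb (1.47), Ier2 (1.32) and Dusp1 (1.30) were at least 2-fold higher, and Btg2 had -0.77. The unfolded protein response list lay inside the central 95% with 2 alternatives and the immediate early list with 5.

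**Figure D2:**
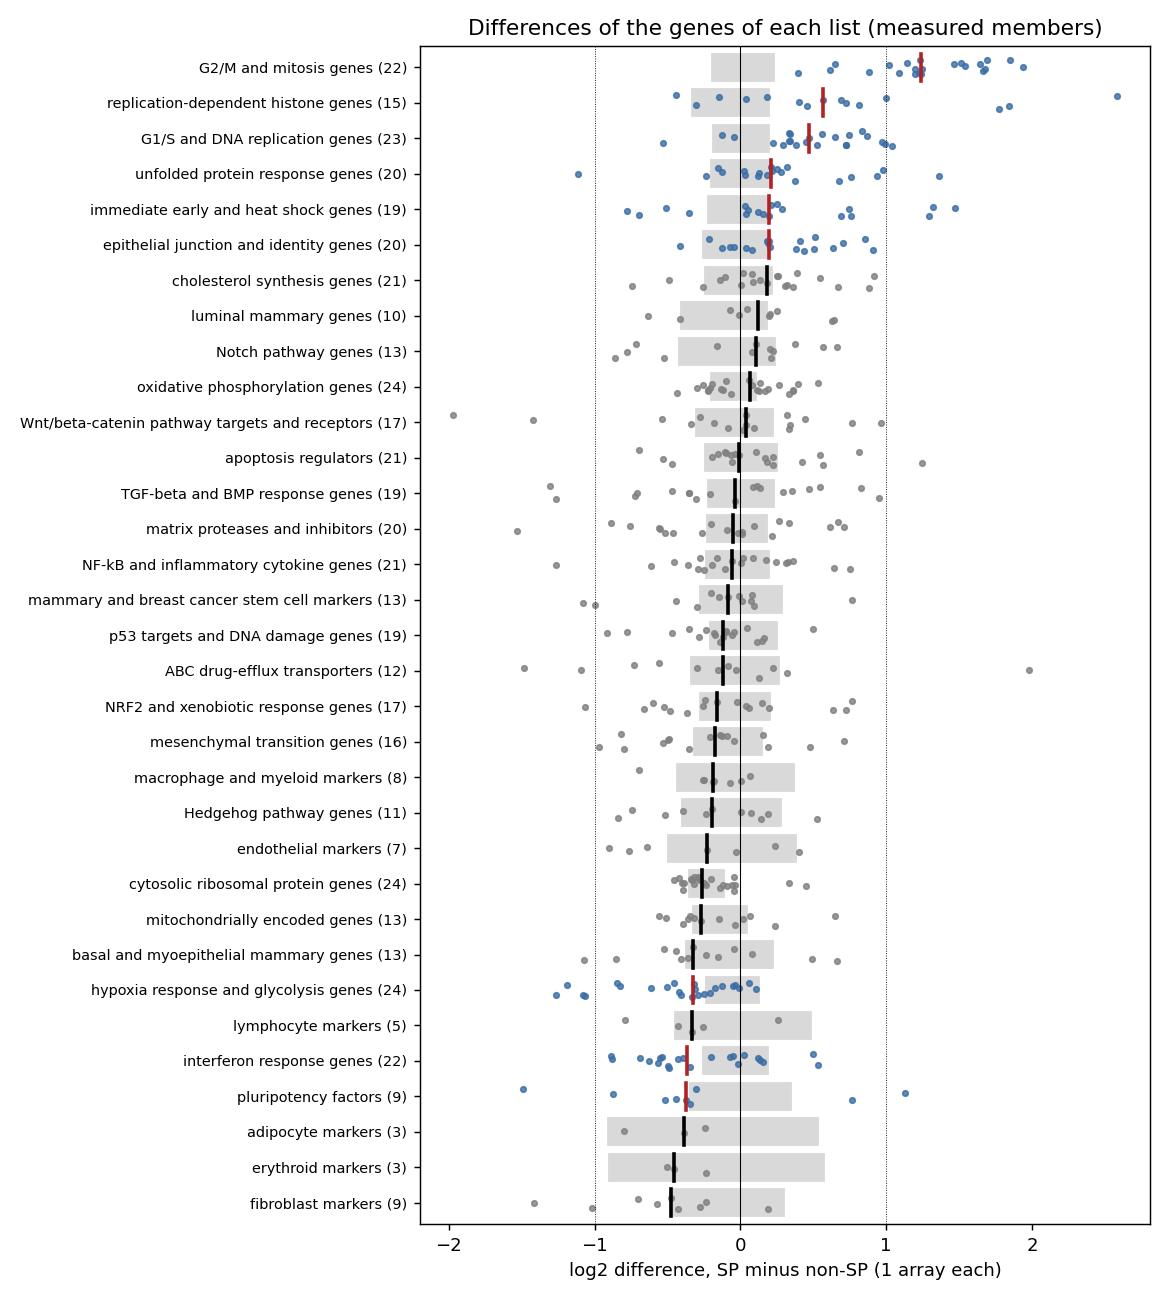
Log2 difference between SP and non-SP (horizontal axis) for the measured members of the 33 gene lists (vertical axis, number measured in parentheses). Points are genes, vertical bars list medians, grey boxes the central 95% of 10000 random lists of like signal, and lists whose median lies outside the box are in colour. Of the 9 such lists, 6 lie above, led by the G2/M list at 1.24, and 3 lie below, whose medians are between 0.06 and 0.10 with spike-in scaling, where their sign is not settled.

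Of the 33 lists, 9 lay outside the central 95% of random lists, where chance would give about 1.65 for independent genes. Genes of a pathway vary together, so the random lists are narrower than a pathway list would be by chance. The other 24 lists gave no such departure with the main settings. Among signalling pathways, Wnt genes had a median of 0.04 (Ccn5 -1.97, Wnt10b -1.42, Wnt5a 0.97). Ccn5 is named Wisp2 on the array. Notch genes had a median of 0.11 (Notch3 -0.86, Rbpj -0.78, Jag1 0.66) and Hedgehog genes one of -0.20 (Hhip -0.84, Cdon -0.74, Gli3 0.53). TGF-beta and BMP response genes had -0.04 (Ltbp2 -1.31, Bmp7 -1.27, Id3 0.95) and NF-kB and cytokine genes -0.06 (Ccl7 -1.27, Tnfaip3 0.75). Matrix proteases had -0.05, with the collagenase gene Mmp13 at -1.53. The p53 target list had -0.12 (Trp53inp1 -0.92), the NRF2 list -0.16 (Hmox1 -1.07, Gclc 0.76) and apoptosis regulators -0.01 (Birc5 1.25, which is also a mitosis gene, and Bid 0.81). Cholesterol synthesis genes had 0.18 and oxidative phosphorylation genes 0.07 (Uqcrc1 0.54, Cox6c -0.44). Of the cholesterol genes, Fdft1 had 0.92 on 1 of its 2 probes, and -0.79 with no filter on dim probes, and Lss had 0.89. Cytosolic ribosomal protein genes had -0.27 and mitochondrially encoded genes -0.27, values that random lists of equally bright genes also gave (percentiles 32.7 and 10.1), and both medians were positive with spike-in scaling. The mitochondrially encoded list lay at percentile 2.23 with the GC trend removed. Of the 2-fold genes in these lists, Hmox1 was under 2-fold with 4 alternatives, Wnt10b with 3, Ltbp2, Bmp7 and Ccl7 with spike-in scaling and Birc5 on its brightest probe. Wnt5a, under 2-fold and dim, had 0.19 with normexp.

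Of the macrophage and myeloid list 8 of 21 genes were measured, with a median of -0.19 and Csf1r at -0.69. Of the lymphocyte list 5 were measured (median -0.33, Cd3e -0.79), of the endothelial list 7 (median -0.23, Kdr -0.90), of the erythroid list 3 (median -0.46) and of the adipocyte list 3 (median -0.39, Retn -0.80). None of these 5 lists lay outside the central 95% of random lists with the main settings. Some measured members were bright: the signals in SP and non-SP were 4.66 and 5.56 for the receptor gene Kdr, 2.97 and 3.30 for Cd4, and 2.01 and 2.80 for Cd3e. Kdr and Cd4 each had 1 of their 2 probes measured. The other Kdr probe was not well above background on either array, and the other Cd4 probe was so in SP only. The macrophage list lay outside with the stricter filter (percentile 1.67) and the endothelial list with no filter (percentile 1.21).

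Among single genes ranked by size of difference, Ins1, an insulin gene, was higher in SP by 3.80 (spot SD 0.23) with signals of 0.26 and -3.54. Its probe lies on chromosome 19, positions 52339385 to 52339444 (mm9). Shoc1 had 2.90, Fbxo45 2.88, the vomeronasal receptor gene Vmn2r4 2.69, Mcemp1 2.55, Slc25a43 2.31, the phosphatase gene Dusp2 2.31, Dntt 2.23 and Nkx2-5 2.14. The kinesin genes Kif18b and Kif2c had 2.53 and 2.06, the separase gene Espl1 2.34, the phosphatase gene Cdc25c 2.10 and the spindle protein gene Dlgap5 2.09. Without background correction these 5 values were 1.24 (Kif18b), 1.09 (Kif2c), 1.52 (Espl1), 1.08 (Cdc25c) and 1.01 (Dlgap5). The signal of Dusp2 was 4.29 in SP and 1.99 in non-SP. Tfpi, an inhibitor of coagulation, had -3.67 on 1 of its 3 probes (chromosome 2, positions 84284179 to 84284238, mm9), and its value was -1.08 with all probes included. Arfgef3 had -3.30, Tcl1b2 -2.99, Gdpd2 -2.60, the glucagon receptor gene Gcgr -2.505, Sapcd1 -2.46, Dus4l -2.28, Adamts10 -2.28, Nyap1 -2.27, Psg28 -2.26, the Wnt agonist gene Rspo3 -2.16, Pamr1 -2.07, Ube2d-ps -2.04 and Cutal -2.03. Slc25a43, Nkx2-5 and Pamr1 were under 2-fold with normexp or without background correction, and Cutal was under 2-fold on its brighter probe. Other dim genes kept a 2-fold difference but were nearer 0 with other background treatments: Ins1 had 1.92 with normexp, and without background correction Shoc1 had 1.46, Fbxo45 1.61, Vmn2r4 1.16, Mcemp1 1.32, Arfgef3 -1.81, Tcl1b2 -1.64, Gdpd2 -1.61, Dus4l -1.32, Dntt 1.26, Sapcd1 -1.56, Adamts10 -1.20, Nyap1 -1.47, Psg28 -1.47, Ube2d-ps -1.31 and Rspo3 -1.22.

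A further 1286 genes were well above background in SP only and 746 in non-SP only, of which 298 and 383 had a bound of at least 2-fold. These counts were 89 and 157 with normexp and 81 and 134 without background correction. A bound sets the brighter signal against the higher of the dim probe's own signal and the lowest signal called well above background on that array. The bound of a gene is the largest over its probes detected on a single array. By this rule, on the probe with the largest bound, Krt36 was at least 15.4-fold higher in SP, Sct at least 15.3-fold, Hsf5 at least 14.3-fold, Rbfox1 at least 13.03-fold and Wt1os at least 12.8-fold. Vmn1r232 was at least 38.7-fold lower in SP, Disp2 at least 35.0-fold, Arl14 at least 34.5-fold, Pbp2 at least 27.1-fold and Rnf150 at least 25.02-fold. Krt36, Disp2 and Rnf150 have 3 probes on the array, and Rbfox1 and Wt1os have 2. Their other probes may not carry the bound. These folds hold for the main background treatment only and were not given for the others. They are not firm minimums, since the limit is the single lowest signal called well above background. In the gene groups above, bounds of at least 2-fold were found in SP for Aurkb, Cenpf and the luminal factor gene Elf5, and in non-SP for Cxcr4, Mmp2, Mx1, Nkd1, Il7r, Dcn and Abcb5.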

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

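Removal of a probe GC trend and spike-in scaling were chosen after seeing the data, and the other 10 alternatives before the data were examined. No paired analysis was possible because each fraction has 1 array, and for the same reason the slide as a block, a replicate block and leave-one-out were not run. Over the 12 alternatives, the G2/M list had medians from 1.21 to 1.67, the G1/S list from 0.47 to 0.90 and the histone list from 0.147 to 1.0005, all 3 above the central 95% of random lists. Abcg2 ranged from 1.87 to 2.41. The hypoxia and interferon lists lay below the central 95% in all 12. Scaling to the median or to the spike-ins adds a constant to all genes, so neither could change a percentile. Spike-in scaling moved all genes up by 0.43. The medians of the 3 lists below the central 95% with the main settings then became positive: hypoxia 0.10, interferon 0.063 and pluripotency 0.062. With the main scaling these 3 medians lay within the range of the 8 spike-in probes (-0.72 to -0.30), so their sign relative to the spike-ins is not settled. Most other negative list medians also became positive, among them those of ABC transporters (0.31), mesenchymal genes (0.26) and basal genes (0.11). Spike-in scaling gave 1829 genes at least 2-fold higher, 150 lower and 237 with a bound in non-SP. Scaling to the median gave 989 higher and 271 lower. These shifts follow from the scaling, which adds a constant. For the values below the cause was not tested. Normexp gave 196 higher and 145 lower genes, bounds for 89 in SP and 157 in non-SP, and medians of 0.15 for histones and -0.15 for Notch genes. Without background correction these were 194, 129, 81, 134, 0.16 and -0.14. With quantile normalization the ribosomal median was -0.027, the mitochondrial 0.053 and the erythroid -0.25. The authors' intensities gave -0.027, 0.053 and -0.25 for these, and -0.027 for adipocyte markers. The loess fit gave 380 lower genes and medians of -0.14 (basal), 0.76 (histones), 0.31 (Notch), -0.032 (Hedgehog), -0.031 (ribosomal), -0.026 (mitochondrial), -0.17 (erythroid) and -0.19 (adipocyte). No filter on dim probes gave 1243 higher and 2433 lower genes and medians of -0.37 (ABC transporters), -0.41 (mesenchymal), -0.37 (luminal), -0.18 (Wnt), -0.23 (proteases), -0.42 (macrophage), -0.48 (endothelial) and -0.59 (adipocyte), with the median of all genes moved by -0.23. The stricter filter gave 349 lower genes and -0.42 for macrophage markers, and left no adipocyte marker to give a value. Keeping outlier spots gave -0.23 for adipocyte markers, and the brightest probe per gene gave -0.13 for Wnt and 0.075 for Hedgehog genes. No named gene with a difference of at least 2-fold changed sign with any of the 12. Of the 161 named genes, 118 moved by more than their spot SD with normexp, a count that was not split by signal.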

Other observations

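The loess and preparation tests on G2/M genes and the probe test on Abcg2 were chosen after the results were seen, as were the gene families and bright genes described first. Grouping genes by the stem of their symbol gave 309 families of at least 6 measured genes. Of these, 22 had a median in the upper 0.5% of random lists and 5 in the lower 0.5%, where chance would give about 3.09 in both tails for independent genes. Genes with the stem Mcm, among them subunits of the replicative helicase, had values above 0 in 10 of 10 genes, with a median of 0.68. Nucleoporins (Nup) were above 0 in 18 of 19 genes with a median of 0.53, and subunits of the cytosolic chaperonin (Cct) in 7 of 7 with a median of 0.54. Genes with the stem Eif, translation initiation factors and their regulators, had a median of 0.29 over 52 genes, with Eif5a at 1.54. Mitochondrial ribosomal proteins had medians of 0.25 over 49 large-subunit genes (Mrpl) and 0.32 over 29 small-subunit genes (Mrps). Genes with the stem Psmd, most of them proteasome subunits, had a median of 0.42 over 14 genes.

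Lower values in SP were seen for clustered protocadherins (Pcdhb), dim and near-identical copies, with 7 of 7 genes below 0 and a median of -1.17. Carbonic anhydrases (Car) were below 0 in 10 of 10 genes with a median of -0.52, calmodulin kinases and their inhibitors (Camk) had a median of -0.56 over 10 genes, collagens (Col) one of -0.47 over 19 genes, and olfactory receptors (Olfr) one of -0.43 over 88 dim genes. With spike-in scaling these medians were -0.74 (Pcdhb), -0.09 (Car), -0.13 (Camk), -0.04 (Col) and 0.00029 (Olfr). After the loess fit they were -1.02, -0.52, -0.39, -0.27 and -0.17, with Camk at percentile 0.73 and Col at 1.45, both outside the lower 0.5%. Among the brightest of 5 equal classes of genes by signal, the ubiquitin-conjugating enzyme gene Ube2s had 2.001, Prag1 1.96 and the mitotic kinase gene Plk1 1.54. The secreted protease inhibitor gene Slpi had -1.94 (3.83-fold lower in SP), the lipocalin gene Lcn2 -1.73 (3.31-fold lower) and the matrix protein gene Mgp -1.22. Spot SDs of these genes were at most 0.07. Of the 10 spike-in probes, 8 were well above background, with differences between -0.72 and -0.30 relative to the 75th percentile and a median of -0.38. The probe at -0.72 had a spread of 0.32 (SD of 35 spots), and the other 7 lay between -0.42 and -0.30.

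The higher values of G2/M genes in SP were set against technical trends. Their median was 1.23 after the loess fit, 1.24 after removing a GC trend and 1.26 after subtracting the median of each block of spots. Each lay above the upper limit of random lists (0.23, 0.22 and 0.23), which argues against these trends as the cause. The random lists were matched on signal and so already carried any intensity trend. Against that trend the loess fit therefore adds little to the main comparison. A difference between the 2 preparations that has nothing to do with the sorted fraction stays open, since there was 1 preparation per fraction. A hypothesis is that the SP preparation may have held fewer quiescent cells. With the main scaling, 10 of 12 measured genes of a quiescence list written before the test were below 0. The lowest were Mxd4 (-0.96) and Tob1 (-0.85), and the 2 above 0 were Foxo1 (0.53) and Foxo3 (0.14). Spike-in scaling adds 0.43 to each of these values, so the count below 0 depends on the scaling. The median of that list, -0.21, lay at percentile 14.2 of random lists, which leaves the hypothesis undecided.

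The Abcg2 difference was 26.2 times the spot SD at its signal and 1.95 after the loess fit, which argues against spot noise and an intensity trend. Whether another transcript could bind its probe stays open, since the array has 1 Abcg2 probe. A biological difference between the fractions, which the design names, stays open and untested by replicates.

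In the dimmest of the 5 signal classes, 257 were at least 2-fold lower in SP and 58 higher, whereas the brightest class had 29 lower and 39 higher. Spot noise drawn around no difference gave 2.21 lower genes in the dimmest class, which argues against noise of the drawn size alone. Noise in that class may be larger, since the spot SD was held constant below the dimmest sixth. The median difference of that class was -0.30, so the draw does not bear on noise added to this shift. After the loess fit that class held 106 lower and 134 higher genes, a ratio of 0.791. From the dimmest to the brightest class, the medians before the fit were -0.30, -0.15, -0.02, 0.04 and -0.05, so the differences did vary with signal. The fit centres the differences at each signal level whatever their cause. The balance after the fit therefore does not tell whether a technical trend between the arrays caused that variation, which stays open. A biological explanation was not tested.

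A hypothesis of copy number differences between the fractions was tested by the median difference, after the loess fit, in 141 windows of 20 Mb. Only 1 window went past the 95% limit of 1000 position shuffles: chromosome 2, positions 160000001 to 180000000 (mm9), with 221 genes and a median of -0.14 relative to all genes. A shift of this size may also reflect neighbouring genes that vary together, which was not tested.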
